A study of Caenorhabditis elegans with 2 samples.

How the data were processed

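Per the labels, ChIP-seq was done on whole late embryos of a transgenic C. elegans strain that expresses the K02D7.2 (snai-1) protein fused to GFP, with an antibody against GFP, after shearing the chromatin by sonication. The labels name the tag as eGFP in one field and as GFP-FLAG in another, and 1 field gives the target, K02D7.2, in the place of the antibody. Both samples are biological replicates of 1 group and each has 1 technical replicate, per the labels. Replicate numbers were taken from the labels.

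The authors deposited lists of regions in the narrowPeak format on the genome builds ce11 and ce10. Each build has 1 list of peaks and background regions per replicate, 1 such list for both replicates pooled, and 1 list of peaks that passed an IDR threshold. Per the deposited manifests, the list of each replicate was made from that replicate's alignment and a control alignment, the pooled list from both alignments and a control, and the IDR list from the lists of both replicates and the pooled list. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The values in the seventh column are the caller's signal for each region as deposited by the authors, on a scale that is not stated and that is comparable within 1 list only. The ninth column holds the −log10 q-value of each region as deposited, and the tenth the position of the summit from the region's start, which the authors' format counts from 0. Each candidate list held 30000 regions, so it was limited in number and not by significance. In the pooled ce11 list the lowest −log10 q was 0.0372. The IDR list held 495 regions on ce11 and 487 on ce10. All 495 had the same coordinates and signal as a region of the pooled list and were its 495 strongest. Nearly all regions had a fixed width (456 bp in 99.8% of pooled regions and 89.3% of IDR peaks), so widths were not compared. Read counts were not given in these files, so depth is unknown, and the control library was not analysed here.

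Positions were compared with the Ensembl release 115 annotation of WBcel235, which has the coordinates of ce11, and with the RefSeq sequence of the same assembly. No ce11 region extended past the end of its chromosome. The same held for the ce10 regions, so this check does not tell the builds apart. The ce10 lists were used only for counts, for the share on X and for replicate overlap, and no coordinate was converted between builds. Regions on the 6 nuclear chromosomes were used. Printed coordinates count from 1.

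Before the data were examined, the tests, the gene lists, the alternatives and the rule for named genes were fixed. The main background was the set of 29315 pooled candidate regions that no IDR peak overlapped. Shares on X and in promoters were compared with Fisher's exact test, two-sided. Promoter windows ran from 1000 bp upstream to 200 bp downstream of any annotated transcript start of a protein-coding gene, so that 1 summit could be assigned to more than 1 gene. Motifs were counted in windows of 101 bp at the summit and in windows centred 400 bp to each side, merging each hexamer with its reverse complement. They were tested with the exact McNemar test (two-sided binomial test on discordant peaks) against 1 flank per peak, its side drawn with a fixed seed. The flank percentages printed are the mean of both sides. The 26 preset gene lists, and gene classes named by the letters of the gene symbol, were tested with Fisher's exact test among the 7647 protein-coding genes that had a pooled candidate summit in the same window. Lists needed 5 members and classes 10 members in that background. Adjusted p-values are Benjamini-Hochberg values over the 10 E-box classes, all hexamers, 24 lists or 65 classes. Intervals are exact (Clopper-Pearson) 95% binomial intervals. Replicate overlap was set beside 1000 draws of the same number of random candidate regions. No test between conditions was possible with 1 group.

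The rule for named genes took snai-1, ces-1, scrt-1, unc-119, egl-1, hmr-1 and hlh-2 in every case. It added the genes assigned to the 20 IDR peaks with the highest signal. For each preset list, and each gene class past the threshold, it took up to 4 members with the highest signal, and it took the 5 hexamers with the smallest adjusted p. The host genes and non-coding genes at the strongest peaks were read from the annotation at the summit. The comparisons with tRNA, snoRNA and other non-coding genes, the isotypes (taken from the RefSeq annotation by matching coordinates), the B-box pattern, the dense bins of chromosome III and all subsets of the IDR list built on them were added after the data were seen. Bins were 250 kb wide and counted as dense with 8 or more IDR peaks.

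The alternatives tried were the ce10 lists, the stronger part of the IDR list, the 2N strongest pooled regions, each replicate alone, other overlap rules, other backgrounds, other promoter and motif windows, nearest-gene assignment, matched random gene sets and leaving out 20 kb around snai-1 and unc-119. Leaving out the dense bins, the peaks at tRNA genes, both, and the peaks at tRNA, snoRNA and snRNA genes were added after the data were seen. Across these settings, hexamers past the threshold are given as a percentage of those tested. The tests were checked on simulated data. With no motif planted, the CAGGTG test was called in 0 of 20 runs. A list of ribosomal protein genes given a 5-fold chance of a peak was called in 81 of 100 simulations over 7647 genes, and at a 2-fold chance in 8 of 100. Of 200 random draws of 495 candidate regions, 2 gave an X share with p below 0.05. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.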

Results

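Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the sites occupied by SNAI-1, a zinc-finger transcription factor of the Snail family encoded by K02D7.2, in late embryos of the nematode Caenorhabditis elegans. The worms carried an integrated transgene that makes SNAI-1 with a C-terminal GFP tag in an unc-119 mutant background, and chromatin was recovered from whole mixed-sex embryos with an antibody against GFP. Embryos were collected 5 hours after synchronization by egg bleaching. The series holds 1 group of 2 biological replicates and no second condition. The comparison made here is between the peaks that passed the authors' reproducibility filter and the weaker candidate regions of the same libraries. The files list regions and no read counts, so the sequencing depth of each library is unknown. The exact binomial intervals given below treat peaks as independent and do not include biological variation. Coordinates are on ce11.

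The authors' list of peaks that passed their reproducibility filter (irreproducible discovery rate, IDR) held 495 regions. Its strongest members lay at genes for small non-coding RNAs. The highest signal in the list, 866.2, belonged to a peak on chromosome V (12303440 to 12303813, summit 12303642) over the snoRNA genes C51F7.3 and C51F7.4, inside an intron of frm-7. The next was on chromosome II (11960651 to 11961018) beside the snoRNA gene W03C9.9, with a signal of 840.3. A peak on chromosome X (13665414 to 13665764) over a leucine tRNA gene had a signal of 540.9. Among the 20 strongest peaks, 10 lay within 100 bp of a snoRNA gene and 2 within 100 bp of a tRNA gene. Of the remaining peaks among these 20, the peak on chromosome I (13463809 to 13464066) had its summit in an exon of rpr-1, the RNA of the tRNA-processing enzyme RNase P, with a signal of 437.1. A further peak, on chromosome IV (11026136 to 11026320), lay beside the microRNA gene mir-51, with a signal of 422.8. The authors' signal is a value of each region on a scale that is not stated. It serves here to rank regions and to compare medians within a list.

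The replicates shared most of their strongest sites. Both contained the snoRNA peak in frm-7 at the top of their own lists, at rank 2 in replicate 1 and rank 1 in replicate 2, and the leucine tRNA peak at ranks 9 and 6. Of the 495 strongest regions of replicate 1, 303 were overlapped by at least 1 bp by one of the 495 strongest of replicate 2, which is 61.2% (exact 95% interval 56.8 to 65.5%). Regions drawn at random from each replicate's candidate list overlapped in 1.01% of cases on average over 1000 draws, and in 2.83% at most. The share was 74.5% among the N/2 strongest regions and 48.3% among the 2N strongest, where N is the number of IDR peaks. Across 494 IDR peaks found in both candidate lists, the signal in the 2 replicates had a Spearman rho of 0.64. This correlation runs across peaks, which are not independent replicates. Of the 495 IDR peaks, 305 (61.6%) overlapped one of the 495 strongest regions in each replicate, so the rest were not among the strongest in both. Some named peaks rested mainly on 1 replicate. The peak at mex-1 ranked 151 in replicate 1 and 4860 in replicate 2, and the peak at rps-20 ranked 14449 and 233.

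**Figure D1:**
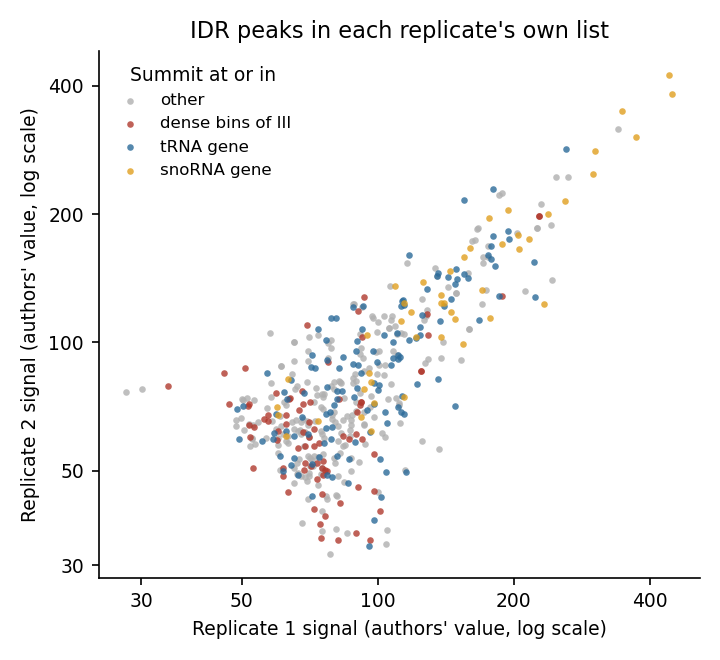
Each point is 1 of 494 IDR peaks, with the authors' signal of the strongest overlapping region in replicate 1 (x axis) and replicate 2 (y axis), both on log scales without units. Colours mark peaks at tRNA genes, at snoRNA genes, in the dense bins of chromosome III and all others. Of the 46 peaks at snoRNA genes, 31 are among the 99 strongest of the list and the others spread to lower signals, and the peaks of the dense bins lie mainly at low signal.

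Many peaks lay at transfer RNA genes. The summits of 26.1% of the 495 IDR peaks (exact 95% interval 22.2 to 30.2%) lay inside a tRNA gene or within 100 bp of it, against 184 of the 29315 pooled candidate regions that no IDR peak overlapped (0.628%). The odds ratio was 55.8 (two-sided Fisher's exact test, p = 2.25e-148; Benjamini-Hochberg adjusted p = 2.02e-147 over 9 non-coding gene classes). Of 612 annotated tRNA genes, 130 (21.2%) had an IDR summit within that distance. They included genes for leucine (11 of 39), glutamate (12 of 41), alanine (10 of 34) and glycine (10 of 55) tRNAs. No isotype differed from the other tRNA genes after adjustment (lowest adjusted p = 1, Fisher's exact test over 22 classes). Of these summits, 88 lay inside a tRNA gene and 27 (20.9%) upstream of its 5′ end, and the median position was 32 bp downstream of that end (interquartile range 6 to 50 bp) in genes with a median length of 72 bp. The strongest 495 regions of each replicate alone gave 116 (23.4%) and 122 (24.6%) at tRNA genes. The non-coding gene classes and their 100 bp distance were chosen after the data were seen.

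Small nucleolar RNA genes, whose products guide the modification of ribosomal RNA, were also frequent at the peaks. Here 46 IDR summits (9.29%, 6.88 to 12.2%) lay within 100 bp, against 59 background regions (0.201%), with an odds ratio of 50.8 (Fisher's exact test, p = 9.53e-54, adjusted p = 2.86e-53). These summits sat mainly in front of the gene, 42 of 46 upstream of its 5′ end, at a median position of -42 bp. The snoRNA peaks were strong as a group, with a median signal of 262.6 against 178.7 for the tRNA peaks. Genes for small nuclear RNAs had 7 summits within 100 bp against 22 in the background (odds ratio 19.1, adjusted p = 8.54e-07, Fisher's exact test). They included sls-2.4, sls-2.2 and sls-2.1, genes for the spliced leader RNA SL2 that is trans-spliced onto downstream operon genes, with signals of 338.9, 197.7 and 192.7. MicroRNA genes had 4 summits against 40 in the background (odds ratio 5.96, adjusted p = 0.0109, Fisher's exact test). Genes that the annotation calls ncRNA without a stated kind, 7764 in number, had the most summits of any class, 149 (30.1%) against 4.59% of the background (odds ratio 8.96, adjusted p = 8.47e-74, Fisher's exact test). Of these 149 summits, 101 also lay at a tRNA, snoRNA or snRNA gene. Among the 313 peaks away from those 3 kinds, 48 (15.3%, 11.5 to 19.8%) lay at such an ncRNA gene, against 4.22% of the background (odds ratio 4.11, p = 2.68e-14, Fisher's exact test). The sls-2 genes were chosen after their values were seen. In all, 182 of the 495 IDR peaks (36.8%) lay at a tRNA, snoRNA or snRNA gene.

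**Figure D2:**
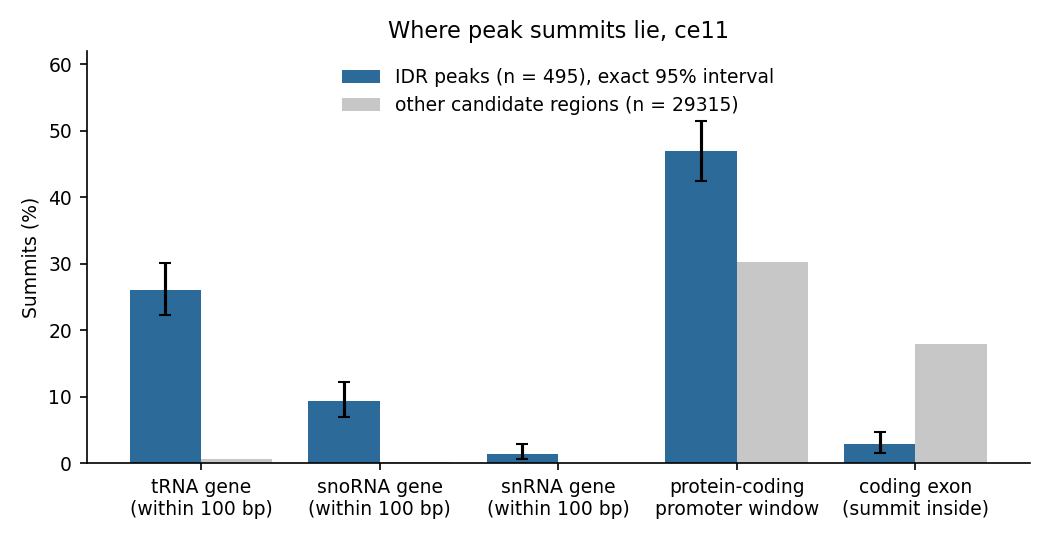
The y axis gives the percentage of summits in each place, for the 495 IDR peaks (blue, with exact 95% binomial intervals) and for the 29315 candidate regions that no IDR peak overlaps (grey). Summits at tRNA genes make up 26.1% of the IDR peaks and 0.628% of the other regions.

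Promoters of protein-coding genes held 232 of the 495 summits (46.9%, 42.4 to 51.4%), against 30.3% of the background regions (odds ratio 2.03, p = 2e-14, Fisher's exact test). The promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated transcript start. Among the strongest of these peaks was one upstream of K12H4.5 on chromosome III (8043794 to 8044124, signal 667.6). Another lay between ears-2, which encodes a glutamyl-tRNA synthetase, and uncp-18 on chromosome IV (390340 to 390648, signal 505.8). A further peak lay between atx-2, the ataxin-2 homologue, and ecps-1 on chromosome III (10461207 to 10461458, signal 490.1). The genes sre-23 and T02E1.2 were also assigned one of the 20 strongest peaks, at signals of 544.6 and 474.1, and in both cases the summit lay within 100 bp of a snoRNA gene. The last genes assigned to these 20 peaks were Y39E4B.6 (413.9), whose peak lay in the dense part of chromosome III described next, and M01F1.9 (408.9). Coding exons held 14 summits (2.83%) against 17.9% of background regions (odds ratio 0.133, p = 2.9e-25, Fisher's exact test). Outside the bodies of protein-coding genes lay 58.2% of summits against 37.8%. This share includes summits inside non-coding genes, such as tRNA genes, and summits in promoter windows. When the peaks at tRNA, snoRNA and snRNA genes were set aside, 185 promoter peaks remained, with a median summit position of -207 bp from the transcript start.

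The peaks were spread unevenly over the chromosomes. Chromosome III held 155 of the 495 (31.3%, 27.2 to 35.6%) against 18.6% of the background regions, an odds ratio of 1.99 (adjusted p = 1.45e-10, Fisher's exact test over 6 chromosomes). Of these, 81 lay in 6 bins of 250 kb between 11750001 and 13500000 on its right arm, each with 8 or more IDR peaks. The bin between 12250001 and 12500000 was not among them, and the densest bin elsewhere held 7. The same 6 bins held 198 pooled candidate regions on average (SD 29.8, 6 bins) against 72.8 (SD 28.9) in the other full bins. The ratio of candidate regions was 2.62 in replicate 1 and 2.57 in replicate 2, and 1.73 and 1.82 against the 9 other full bins of the right arm alone. Peaks in these bins lay at a tRNA gene in 2 of 81 cases, against 127 of the other 414 (odds ratio 0.0572, p = 1.61e-09, Fisher's exact test). The bins hold only 6 annotated tRNA genes, of which 2 had a peak, and against the other candidate regions of the same bins the peaks lay at tRNA genes more often (1 of 1067, odds ratio 27, p = 0.0141, Fisher's exact test). The highest among them were at Y39E4B.6 (413.9), at cox-5A (314.9), which encodes a subunit of cytochrome c oxidase, and at mrg-1 and spcs-2 (255.8). The bins, cox-5A, mrg-1 and spcs-2 were chosen after the data were seen.

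**Figure D3:**
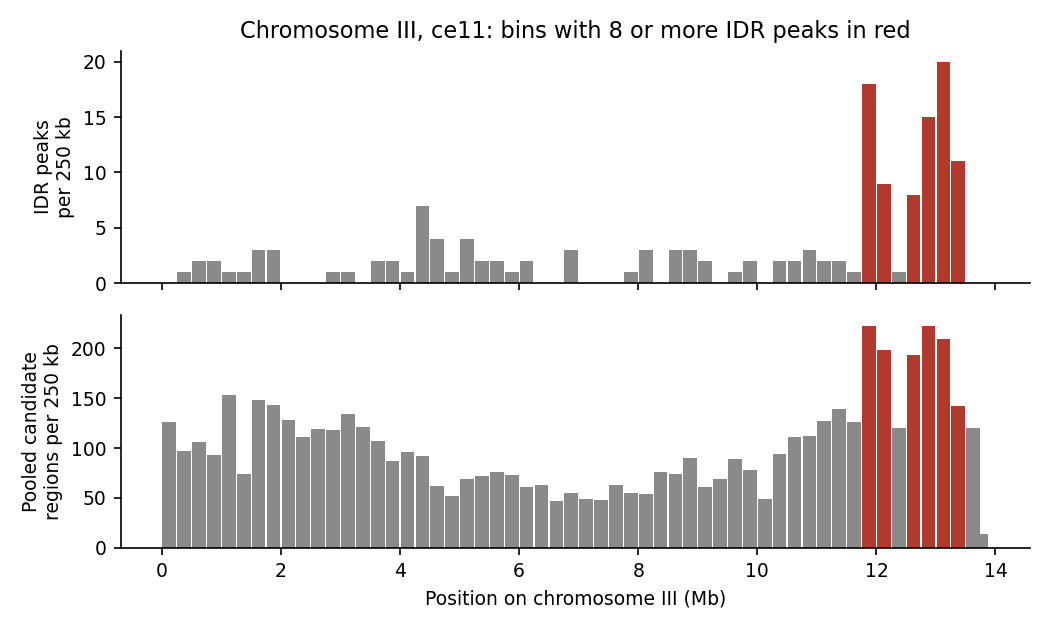
Bars along chromosome III (x axis, Mb) give the number of IDR peaks (top) and of pooled candidate regions (bottom) in each 250 kb bin. The 6 bins in red hold 8 or more IDR peaks each, 81 in all.

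The X chromosome held 93 peaks (18.8%, 15.4 to 22.5%) against 14.4% of the background regions, an odds ratio of 1.37 (p = 0.00815, Fisher's exact test). Peaks at tRNA genes made up 64 of these 93. X carries 276 of the 612 annotated tRNA genes (45.1%), and tRNA genes on X had an IDR peak about as often as those on the autosomes (65 of 276 against 65 of 336, odds ratio 1.28, p = 0.233, Fisher's exact test). Without regions at tRNA genes, X held 29 of 366 peaks (7.92%, 5.37 to 11.2%) against 14.3% of the background, and the direction turned (odds ratio 0.516, p = 0.00028, Fisher's exact test). Against random genomic positions in place of candidate regions, the share on X did not pass the test (odds ratio 1.08, p = 0.513, Fisher's exact test).

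The hexamer CAGGTG, the E-box bound by Snail-family proteins in many animals, was not enriched at the summits. It was present, on either strand, within 50 bp of 8 of the 495 summits (1.62%, 0.7 to 3.16%), against a mean of 3.23% in windows of the same size centred 400 bp to each side (p = 0.0931, exact McNemar test against 1 flank drawn per peak). Over 100 other draws of the flank side the p of this exact test had a median of 0.134, ran from 0.00936 to 0.648 and was under 0.05 in 20. In simulations, windows taken from the flanks of candidate regions stood in for the summits, and CAGGTG was planted on top of its natural occurrences. Planted in 5% of 495 windows it was called in 16 of 20 runs, and in 10% in 20 of 20. These windows were not matched to the real summits in GC content or small RNA genes, so the rates may differ there. None of the 10 classes of CANNTG E-box passed a Benjamini-Hochberg adjusted p of 0.05, and 1 class, CACTTG (the reverse complement of CAAGTG), had an unadjusted p below it. CACTTG was present at 7.68% of summits and 3.33% of flanks (exact McNemar test, p = 0.0198, adjusted p = 0.198). Its adjusted p was below 0.05 in 59 of 100 draws of the flank side. Among the 185 promoter peaks away from tRNA, snoRNA and snRNA genes, a subset chosen after the data were seen, CACTTG was present at 12.4% of summits (8.05 to 18.1%) and 2.16% of flanks (exact McNemar test, adjusted p = 0.000359 over 10 classes, below 0.05 in 100 of 100 draws). Flanks and summits differ in GC content, which these draws do not address. With all IDR peaks set against candidate windows of matched GC content, 0 of the 10 classes passed. That comparison did not cover the 185 promoter peaks alone.

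**Figure D4:**
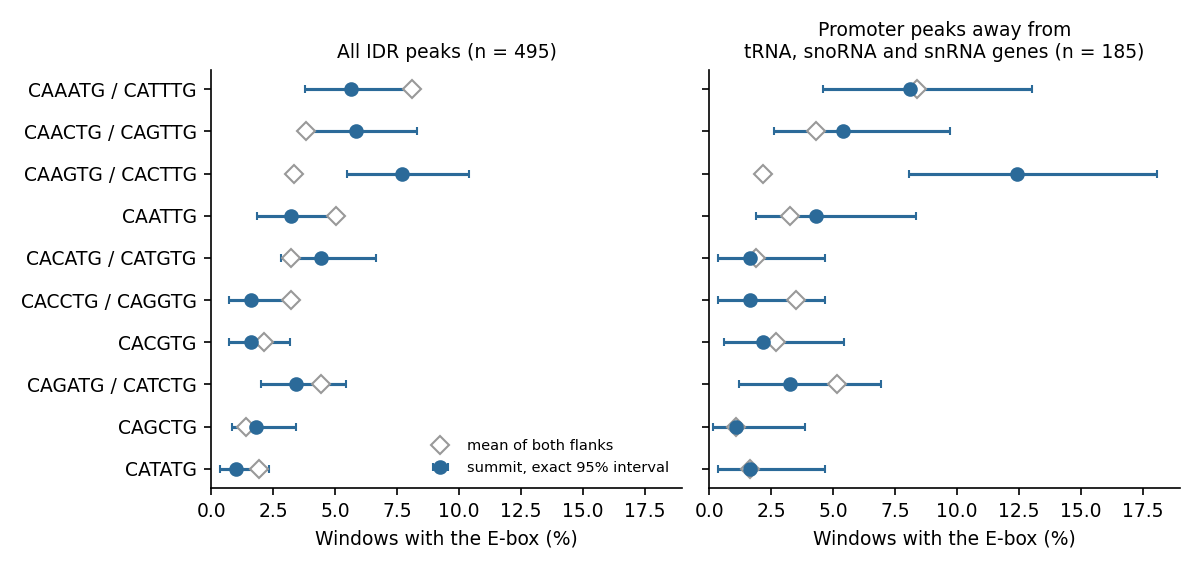
For each E-box class (y axis, with its reverse complement), the x axis gives the percentage of windows that contain it, at summits (blue, exact 95% intervals) and as the mean of both flanks (open diamonds). The left panel shows all 495 IDR peaks and the right panel the 185 promoter peaks away from tRNA, snoRNA and snRNA genes, where CACTTG stands at 12.4% against 2.16%.

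Other hexamers were strongly enriched. Over all hexamers, 280 (13.5%) were more frequent and 221 less frequent at summits than in flanks at an adjusted p below 0.05. The smallest adjusted p belonged to ACCACT, present at 16.6% of summits and 2.02% of flanks (exact McNemar test, adjusted p = 5.25e-13), followed by CGAACC (14.5% against 1.82%), GTTCGA (18.2% against 3.64%), GAACCC (13.7% against 2.42%) and ACGCGC (11.3% against 1.31%). GTTCGA is the core of the B box, the internal promoter element of tRNA genes. It was present at 48.1% of the summits at tRNA genes, where the flanks had 4.65%. CGAACC and GAACCC overlap GTTCGA in 1 longer sequence, and were present at 41.9 and 38.8% of these summits. ACCACT was present at 39.5% of them. A longer B-box pattern (GTTCGA, any 2 bases, then C) was found within 100 bp of 69.8% of the summits at tRNA genes (90 in all), 17 of the 46 at snoRNA genes and 2 of the 185 promoter summits away from small RNA genes. The summits at tRNA genes were chosen for their distance to genes that carry this element. Its high share there therefore restates that choice, and tRNA genes without a peak were not compared. In those promoter peaks the leading hexamers were CGCGCC (18.9% against 1.35%, adjusted p = 1.55e-06, exact McNemar test), CCGCAC (21.1% against 1.62%) and GCCGCA (21.6% against 1.08%). Summit windows had a mean GC content of 47.8% and the flanks 36.6 and 36.2%. Against summit windows of other candidate regions with matched GC content, 2.26% of hexamers passed with Fisher's exact test. That comparison was unpaired, so its test and its windows differ from the flank test as well as the GC content.

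Genes for ribosomal proteins were the 1 preset list of 24 past the adjusted threshold with Fisher's exact test. In all, 310 protein-coding genes had an IDR summit in their promoter window, out of 7647 with a candidate summit there. Of 61 ribosomal protein genes among those 7647, 11 had a peak (18%, 9.36 to 30%), against 3.94% of the other genes (odds ratio 5.36, adjusted p = 0.000665 over 24 lists, Fisher's exact test). The highest signals were at rpl-3 on chromosome III (3867475 to 3867697, signal 387.3), rpl-15 (220.2), rpl-35 (218) and rpl-20 (205.4), all proteins of the large subunit. Small subunit genes were also among them, and the gene class rps was the 1 class of 65 to pass (6 of 25 genes, odds ratio 7.6, adjusted p = 0.0253, Fisher's exact test). Its highest signals were at rps-28 (176.1), rps-26 (171.8), rps-19 (168) and rps-24 (154.2). The summit at rps-26 lay within 100 bp of a snoRNA gene. Several of these summits were also assigned to a neighbouring gene, namely those at rpl-15, rpl-20, rps-28, rps-26, rps-19, rps-1 and rps-20. Among all IDR peaks, 78 of the 232 assigned ones had 2 or more genes. Which gene such a peak belongs to cannot be told here. The list missed the threshold against 10000 random gene sets matched on the distance to the upstream neighbour (permutation test, adjusted p = 0.0768, with 3.86 members at a peak on average). The class rps did not pass in replicate 1 alone, in the stronger part of the list (the N/2 strongest IDR peaks), with the window of 2000 to 500 bp or with the nearest start alone.

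Heat shock genes followed, with 3 of 11 members at a peak (27.3%, 6.02 to 61%, odds ratio 8.95, adjusted p = 0.103, Fisher's exact test). The members were hsp-60, the mitochondrial chaperonin (signal 243.9), hsp-1, a member of the Hsp70 family (137.3), and hsp-90 (120.4). The list passed the threshold in replicate 1 alone and with all protein-coding genes as background. It missed it in every other setting, among them replicate 2 alone and matched random gene sets (permutation test, adjusted p = 0.348). The peak at hsp-90 ranked 253 in replicate 1 and 3748 in replicate 2. Nuclear hormone receptors had 4 of 90 members at a peak, namely nhr-255 (276.9), nhr-41 (145.1), nhr-95 (139.3) and nhr-142 (129.5). Serpentine chemoreceptor genes had 6 of 165, among them sre-23 (544.6), sre-1 (241), sri-5 (160.5) and srh-269 (154.8). The summits at nhr-255, nhr-41 and srh-269 lay at tRNA genes. The adjusted p of both lists was 1.

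Lists for tissues and pathways of the embryo had few or no members at a peak, as did random lists of their size. Of 24 lists tested, 15 had none, among 5 to 51 members each. These were bHLH factors (18 members in the background), neuronal transcription factors (13), body muscle genes (30), pharynx genes (7), intestine genes (6), epidermis genes (10), collagens (51), cell death genes (14), epithelial adhesion and polarity genes (21), cell cycle genes (20), Wnt pathway genes (13), Notch pathway genes (6), axon guidance genes (16), Hox genes (5) and the ceh homeobox class (33). Matched random sets of the same sizes had between 0.0902 (Hox genes) and 2.05 (collagens) members at a peak on average, so an absence of members does not set these lists apart. The exact interval reached 6.98% for the 51 collagens, 11.6% for the 30 body muscle genes and 52.2% for the 5 Hox genes. Several lists had 1 member at a peak. These members were syd-2 of 15 pan-neuronal genes, a liprin of the presynaptic zone (signal 131.1), and flp-23 of 40 neuropeptide genes (144.5), whose summit lay in a proline tRNA gene. The others were daf-19 of 13 cilia genes, the RFX factor of ciliated neurons (133.2), mex-1 of 8 germline genes (140.1), and his-72 of 21 histone genes, which encodes a variant of histone H3 (121.6). None of these lists passed, and each had an adjusted p of 1. The Snail family (1 member in the background) and T-box factors (4) were too few to test and had no member at a peak.

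None of the 7 genes fixed in advance for individual report had an IDR summit in its promoter window. For snai-1 itself (chromosome IV, 311484 to 313715), the window held 1 candidate region at rank 4737 of the pooled list. An IDR peak within 20 kb of snai-1 lay on chromosome IV (322445 to 322900, signal 288.2, rank 60), in the promoter window of grl-26 and at an aspartate tRNA gene. It ranked 59 in replicate 1 and 53 in replicate 2. The locus had 20 candidate regions within 20 kb, and the genome 12 per 40 kb on average. For unc-119 (chromosome III, 10902641 to 10908935), which is mutated in this strain, 29 candidate regions lay within 20 kb, the strongest at rank 907, and none was an IDR peak. No IDR peak lay within 20 kb of ces-1, a Snail-family gene that controls the death of specific neurons, or of scrt-1. The same held for egl-1, the activator of programmed cell death, for hmr-1, which encodes cadherin, and for hlh-2, the partner of bHLH factors. Their strongest candidate regions within 20 kb stood at rank 3180 for ces-1, 2362 for scrt-1, 894 for egl-1, 756 for hmr-1 and 4764 for hlh-2.

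Peaks at snoRNA genes and in the dense bins changed in share along the signal ranking. Of the 99 strongest IDR peaks, 31 (31.3%, 22.4 to 41.4%) lay at snoRNA genes, and none of the 99 weakest did (p = 5.71e-11, Fisher's exact test). Peaks at tRNA genes made up 30.3% of the strongest 99 and 17.2% of the weakest (odds ratio 2.1, p = 0.0443, Fisher's exact test), but their share did not follow the ranking, with 40.4, 27.3 and 15.2% in the 3 sets of 99 between, strongest first. The dense bins of chromosome III held 4 of the strongest 99 and 27 of the weakest (odds ratio 0.112, p = 7.34e-06, Fisher's exact test). The promoter share was 45.5% in both (odds ratio 1, p = 1), and CAGGTG was present at 1 of the strongest and 3 of the weakest (p = 0.621, Fisher's exact test for both).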

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

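Over 130 alternative values, 74 of them planned, 96 kept their direction and side of the threshold or moved little. The promoter, tRNA gene and snoRNA gene shares kept both under every alternative run, with odds ratios of 1.56 to 3.69, 24.6 to 281.6 and 6.61 to 90.6, and which of tRNA and snoRNA genes had the higher one changed between settings. The X share lost its call against random positions (odds ratio 1.08). It turned without peaks at tRNA genes (0.516), without these and the dense bins (0.646) and without peaks at tRNA, snoRNA and snRNA genes (0.611). These 3 settings were chosen after seeing the data. Replicate overlap was 74.5% for the N/2 strongest regions and 48.3% for the 2N strongest. The difference in CAGGTG share between summits and flanks, in percentage points, stayed below 0 in every alternative. It passed the test at -2.43 in the N/2 strongest IDR peaks, -0.909 in the 2N strongest, -3.13 within 100 bp and -2.22 against GC-matched windows. Each of these rests on a single draw of the comparison windows, and the GC-matched windows were compared with an unpaired Fisher's exact test. The difference shrank from -1.62 to -0.707 without replicate 1 and to -0.303 within 25 bp. E-box classes past the threshold numbered 2 in the 2N strongest (CAACTG and CAAGTG). CAAGTG made it 1 without the dense bins, 1 without peaks at tRNA genes and 1 without peaks at tRNA, snoRNA and snRNA genes. Leaving out tRNA peaks and dense bins together gave 0, and each replicate alone gave 0 to 1. Each of these counts rests on 1 draw of the flank side. In the full list CAAGTG passed in 59 of 100 draws, so changes between 0 and 1 may reflect the draw. Hexamers past the threshold made up 8.27% of those tested with the N/2 strongest, 5.72% within 25 bp and 2.26% against GC-matched windows (unpaired Fisher's exact test). They made up 5.43% without peaks at tRNA genes, 6.15% without these and the dense bins, and 2.6% without peaks at any of the small RNA genes. Genes with a peak numbered 171 in the N/2 strongest and 566 in the 2N strongest. Gene lists past the threshold were 2 with all protein-coding genes as background, 0 against matched random sets and 1 to 2 with each replicate alone. The ribosomal protein list passed in 14 of 14 settings with Fisher's exact test (highest adjusted p 0.0257). Gene classes were 0 in the N/2 strongest, 2 in the 2N strongest, 2 and 0 with the windows of 500 to 100 bp and 2000 to 500 bp, and 0 with the nearest start. They were 3 with all protein-coding genes, 2 without peaks at the small RNA genes and 0 to 1 with each replicate alone. Where no construction shows it, the cause was not tested. Depth is unknown, so its effect on weak peaks was not tested. No paired analysis was possible because the series has 1 group.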

Other observations

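Genes for nuclear pore proteins came closest to the threshold among the gene classes that missed it. Of 15 npp genes with a candidate summit, 4 had an IDR peak (26.7%, odds ratio 8.71, adjusted p = 0.0824, Fisher's exact test over 65 classes). They were npp-8 on chromosome IV (1595753 to 1596208, signal 224.6), npp-6 (178.8), npp-14 (131.9) and npp-16 (121.8), all chosen after their values were seen. The class passed with the 2N strongest regions, with the promoter window of 500 to 100 bp and with all protein-coding genes as background. It also passed without peaks at tRNA, snoRNA and snRNA genes. The class missed the threshold in every other setting run, among them each replicate alone, the stronger part of the IDR list and the wider promoter window. It also missed it with the nearest transcript start and when only the peaks at tRNA genes were left out. At the 185 promoter summits away from small RNA genes, 23 windows held CACTTG and 7 of these held CACTTGCG, while neither flank window of any of these peaks held CACTTGCG.

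Except for the CAGGTG share in the strongest peaks, which was planned, the tests that follow were chosen after the result was seen. The bounds of all of them were recorded after the values. The series has 1 group, so no biological explanation was tested against another condition.

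The peaks at tRNA genes have 2 features that technical explanations address. Identical copies of a tRNA gene can share reads, but how the aligner treated such reads is not known here. The tRNA genes with identical copies had a peak more often than those of unique sequence (odds ratio 2.18, p = 0.00342, Fisher's exact test), so shared reads may add to this pattern. The share did not rise steadily with copy number. It was 12.6% for single-copy genes, 28% with 2 to 5 identical copies and 23% with more than 5. At tRNA genes with no like copy and no tRNA neighbour within 1000 bp lay 3 peaks, against 8 background regions (odds ratio 22.3, p = 0.00068, Fisher's exact test). Reads shared between copies do not account for these 3. Only 3 of 36 such genes had a peak (8.33%, 1.75 to 22.5%), against 21.2% of all tRNA genes. So few peaks cannot show how much of the pattern shared reads make up. GC content leaves a pooled odds ratio of 27.7 within GC deciles (21.2 to 36.2, Mantel-Haenszel), and CAGGTG was present at 0.775% of tRNA summits, at most 4.24%, which argues against recognition of that hexamer there. Other E-box classes at these summits stay open, the largest excess being CACATG at 11.6% against 3.88% of flanks (exact McNemar test, adjusted p = 0.207). Signal that many tagged or untagged samples share at highly transcribed genes stays open for the peaks at tRNA, snoRNA, snRNA and ribosomal protein genes alike, as no mock or untagged immunoprecipitation was analysed here.

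The dense bins of chromosome III had raised numbers of candidate regions in both replicates, by a ratio of 2.57 or more (1.73 or more against the rest of the right arm), and median candidate signals 1.26 and 1.25 times those of other bins. Extra copies of these segments in the strain, relative to the control library, may raise both, but they cannot be told apart from a broad domain of signal, because no coverage of the control was analysed here. Against a simple clustering of the usual kinds of sites, away from small RNA genes the promoter odds ratio over local candidate regions was 1.36 in these bins and 5.2 elsewhere, a ratio of 0.261 (0.146 to 0.468, Woolf interval). The low share of tRNA genes among these peaks decides nothing, since the bins hold only 6 of them. The number of transgene loci (snai-1, unc-119) inside these bins was 0, so copies of those loci alone do not account for them.

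The lack of a CAGGTG excess was not explained by the peaks at tRNA genes or in the dense bins. Among the 287 peaks left without them, 2.44% held CAGGTG (at most 4.96%) against 4.01% in the flanks. Among the 99 strongest peaks the share was 1.01% (at most 5.5%). For these 99 as a set, this share argues against CAGGTG sites that are limited to the strongest peaks. Of the 99, 63 lay at tRNA, snoRNA or snRNA genes. The share was not computed for the strong peaks elsewhere, so CAGGTG sites limited to those were not tested. Recruitment of SNAI-1 through other proteins and recognition of the CACTTG class at promoters are untested hypotheses, and nothing analysed here separates them.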
